A study of Mus musculus with 12 samples.

How the data were processed

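RNA of hippocampus and cerebellum from Ercc1-/- mice (KO) and wild type littermates (WT) at postnatal day 21 was hybridised to Affymetrix Mouse Genome 430_2.0 arrays, 1 sample per array and 3 arrays per group, per the labels. Per the labels the mice came from FVB and C57BL/6 crosses, and both regions were taken from 3 KO and 3 WT mice. The labels do not say whether a replicate number names a mouse.

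The authors deposited linear intensity values per probe set and array, made with dChip, software that fits a model to the probes of a probe set, in 1 table per region. The dChip version, the background step and the array normalization are not given in the sources used here. The deposited tables also hold the authors' mean intensity and the standard error of each group. A further deposited short list per region gives, for the probe sets the authors selected, a gene name, a signed fold change and an unadjusted p-value. The signed fold change, negative where KO is lower, is a score that the authors made with dChip from the deposited group means, per the file headers. The deposited value matrix of the whole series equals the region tables (largest difference 0), so using it in their place moves nothing. No sample column was left unused (0 columns). No pair of arrays held identical values.

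The deposited tables carry no gene names outside the short lists. The lists name 610 probe sets, of which 538 have 1 current symbol, 21 name several genes and 51 have no current symbol. Symbols were brought up to date with the RefSeq gene table of assembly GRCm38.p6, used for names only, 4 through the accession and 42 through a synonym, which left 486 distinct genes. Genes therefore could be named only where the authors had selected them in 1 of the regions, and the comparisons were tested on probe sets, not on 1 probe set per gene as planned.

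Values were analysed as log2(value + 32), so a fold change understates the change of dim probe sets. Control probe sets were left out, and probe sets entered a region when their mean log2 value over its 6 arrays lay above the 40th percentile, which kept 27022 in each region and 23283 in both. KO was compared with WT within each region with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with Benjamini-Hochberg adjustment at 0.05. The difference of the KO effect between regions was tested in 1 limma fit over all 12 arrays; because the regional tables were separate, levels were not compared between regions. Adjusted p-values of gene lists below come from camera and all others from limma, unless another test is named. The limma p-values measure the spread between these arrays. Those of camera compare the genes of a list with the other probe sets, and at the preset correlation they rest mainly on the spread between probe sets.

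Before the data were examined, 29 gene lists (pathways and cell type markers) and the rule for named genes were fixed. A list was tested with camera (preset correlation 0.01, and with an estimated correlation as an alternative) when at least 5 of its genes could be named and measured; 3 lists reached this, cholesterol biosynthesis, astrocyte markers and microglia markers. Each gene was represented by its brightest named probe set over all arrays. Named in each region were Ercc1, the 4 probe sets with the smallest p in each direction where none passed, 4 members with the smallest p of each list that passed, and the measured cholesterol genes; some genes under this rule are not reported here. For the regional difference, the rule named the probe sets past the threshold, at most 4 in each direction. Genes named outside this rule are said to be so.

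The limma step was tested on simulated data made from the real means and residual spread of each region, with 200 of 27022 probe sets changed. For hippocampus, 78% of probe sets changed by 1 log2 unit and 22% of those changed by 0.5 were called, and for cerebellum 70% and 28%. The simulation draws independent residuals, so it leaves out structure shared by many probe sets.

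Alternatives changed 1 choice at a time, except that an unadjusted p was joined with a 1.5-fold cut: the pseudocount, the filter, the normalization, the probe sets per gene, the intensity trend, 1 fit over all arrays, a replicate block, the threshold, the correlation used by camera, and each array left out in turn. Added after the data were seen were a covariate for the leading residual component of a region, list tests on members outside the authors' list of the same region, and the mean of both regional effects. Exact permutation tests were two-sided. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used for file handling, exact tests of overlap and plots.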

Results

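Expression was profiled in hippocampus and cerebellum of KO and WT mice at postnatal day 21. Ercc1 is the partner of the nuclease Xpf and acts in nucleotide excision repair and in the repair of crosslinks between DNA strands. The 12 arrays fall into 4 groups of 3, by region and genotype, and each array measured 45037 probe sets other than controls. The median intensity of an array lay between 160.2 and 168.2 in hippocampus and between 154.4 and 168.2 in cerebellum. The number of arrays limits the precision.

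Ercc1 itself was lower on every KO array than on every WT array of the same region. In hippocampus its intensity was 60.2 ± 9.0 in KO and 195.9 ± 24.3 in WT (SD, n = 3 each), a log2 change of -1.30 ± 0.12 (SE). In cerebellum it was 63.6 ± 7.3 in KO and 169.6 ± 54.1 in WT (SD, n = 3 each), a log2 change of -1.04 ± 0.19 (SE). The exact permutation p was 0.1 in both regions, the smallest that 3 against 3 arrays allow. The adjusted p was 0.141 in hippocampus and, in the fit without a filter because the probe set was too dim there, 0.485 in cerebellum. Whether this probe set lies in the disrupted part of the gene is not given in the sources used here.

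The title of the series names cholesterol synthesis in the forebrain, and the hippocampus comparison addresses it. All 7 measured genes of the cholesterol biosynthesis list were lower in KO hippocampus, and the list fell as a group, with a median log2 change of -0.56 (adjusted camera p = 2.91e-18, and adjusted p = 0.0269 with an estimated correlation). Idi1, which isomerises isopentenyl diphosphate, had the largest difference, -0.96 ± 0.12 (SE, n = 3 per group). Hmgcs1, the synthase upstream of HMG-CoA reductase, had -0.56 ± 0.13, and Fdft1, squalene synthase, had -0.50 ± 0.10. The later sterol enzymes Cyp51, Nsdhl and Msmo1 had -0.61 ± 0.13, -0.57 ± 0.15 and -0.52 ± 0.13. Of the list, 7 of 22 genes could be named, and all 7 were in the authors' own hippocampus list, chosen on these arrays. Neither their direction nor the p-values of the list are therefore independent evidence. None of the 7 passed over all probe sets (0). When adjusted over the list alone 7 passed, which the choice of genes by their p on these arrays favours. The 4 named myelin genes, outside the rule and chosen after their values were seen, had log2 changes below 0 in KO hippocampus as well, with a median of -0.328: Ermn -0.75 ± 0.17, Mal -0.36 ± 0.12, Mbp -0.29 ± 0.09 and Mobp, with overlapping groups, -0.25 ± 0.14. None of them passed, and they are too few for a list test. The named probe set of Mbp was dim beside those of Mal and Mobp (WT hippocampus mean log2 value 8.615 against 12.731 and 12.65).

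**Figure D1:**
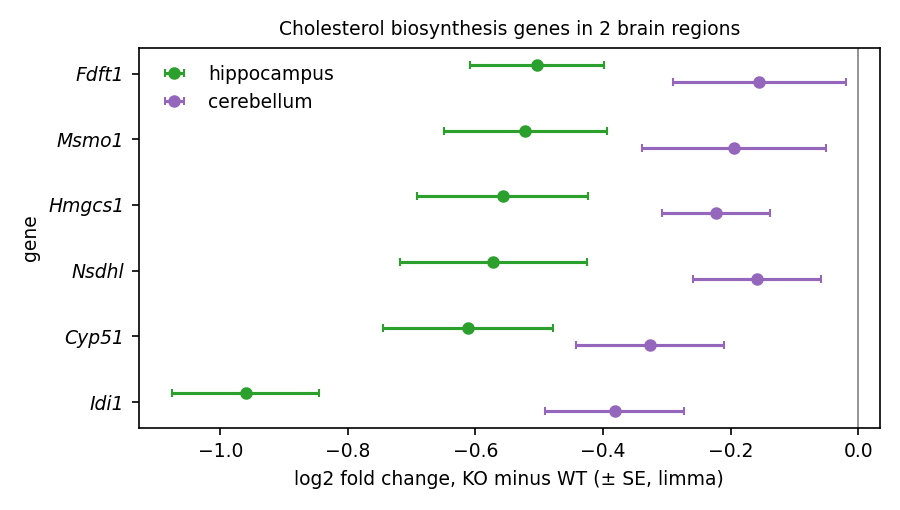
Log2 fold change (KO minus WT, horizontal axis) of 6 cholesterol biosynthesis genes (vertical axis) in hippocampus (green) and cerebellum (purple), with the limma SE as bars, from 3 arrays per group. All 6 lie below 0 in both regions, from -0.96 to -0.50 in hippocampus and from -0.38 to -0.15 in cerebellum.

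Astrocyte and microglia genes were mostly higher in KO hippocampus. Of 5 astrocyte genes 4 were higher, with a median log2 change of 0.34. The aldolase gene Aldoc had 0.59 ± 0.09 and the gap junction gene Gjb6 had 0.40 ± 0.10, while the water channel gene Aqp4 had -0.45 ± 0.08 (SE, n = 3 per group). The brightest probe set of Gfap, the intermediate filament of astrocytes, had 0.34 ± 0.19 with overlapping groups. The list passed at an adjusted p of 0.0106, and not with an estimated correlation (adjusted p = 0.0620). Of 7 microglia genes 6 were higher, with a median of 0.15, at an adjusted p of 0.000124 that also did not hold with an estimated correlation (adjusted p = 0.0512). The protease gene Ctss had 0.25 ± 0.06, the complement genes C1qc and C1qa had 0.37 ± 0.10 and 0.43 ± 0.27, and Tyrobp had 0.15 ± 0.09. The authors' hippocampus list holds 4 of the 5 astrocyte genes, so that list is not independent evidence, and 1 of the 7 microglia genes. The other 6 microglia genes had a median of 0.13, in a test added after the data were seen (adjusted camera p = 0.00169, and adjusted p = 0.0553 with an estimated correlation). No other list was tested there, so the adjustment changed nothing. These 6 genes had been chosen on cerebellum arrays of the same mice, so noise shared by the regions could carry their sign over. Adjusted over the list alone, 3 astrocyte and 2 microglia genes passed, against 0 over all probe sets. The astrocyte genes that passed were Aldoc and Gjb6, which were higher, and Aqp4, which was lower, all chosen on these arrays.

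No probe set passed the threshold in hippocampus (0 higher and 0 lower of 27022), and 1003 had an unadjusted limma p under 0.05 where 1351 would be expected by chance. The probe sets with the smallest p that were higher were 2 of Gfap, at 1.07 ± 0.10 and 0.66 ± 0.08, the sulfotransferase gene Sult1a1 at 1.06 ± 0.12, and Fam107a at 0.45 ± 0.06 (SE, n = 3 per group). Those that were lower were Ercc1, the hydrolase gene Nudt19 at -0.85 ± 0.08, Idi1, and the immunoglobulin gene Ighm at -0.84 ± 0.11. Their adjusted p lay between 0.141 and 0.340, so none passed. With 1 fit over all 12 arrays, which shares the spread between regions, 1 probe set passed as higher and 5 as lower. The arrays part along a line that crosses genotype, with KO 1, KO 3 and WT 1 on one side, and within the sides the median of the cholesterol genes was -0.46 and -0.71 against -0.56 over all arrays. Each side has 1 genotype with 1 array only, and the 7 genes have no overlap of KO and WT over the 6 arrays, so the sign within the sides was fixed beforehand.

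In KO cerebellum, microglia and astrocyte genes were higher. All 7 microglia genes were higher and rose as a group, with a median log2 change of 0.93 and a range from 0.53 to 1.13 (adjusted camera p = 4.00e-21, and adjusted p = 0.0135 with an estimated correlation). Ctss had 1.13 ± 0.09, C1qa 0.96 ± 0.14 and the lysosomal membrane gene Laptm5 0.86 ± 0.15 (SE, n = 3 per group). Of 5 astrocyte genes 4 were higher and the list rose, with a median of 0.79 (adjusted p = 1.60e-11, and adjusted p = 0.0135 with an estimated correlation). Gfap had 1.16 ± 0.13, Gjb6 0.88 ± 0.12, Aldoc 0.79 ± 0.11 and the glutamine synthetase gene Glul 0.51 ± 0.09. The authors' cerebellum list holds all 7 microglia genes and 4 of the 5 astrocyte genes, so these counts and p-values are not independent evidence. Adjusted over the list alone, 7 microglia and 4 astrocyte genes passed, which the same choice favours, against 0 over all probe sets. Genes of other cell types, outside the rule and chosen after their values were seen, had log2 changes away from 0 in KO cerebellum as well; none passed, and they are too few for a list test. The 4 myelin genes had a median of 0.331 (Mal 0.52 ± 0.10, Mobp 0.40 ± 0.10, Ermn 0.26 ± 0.10 and, with overlapping groups, Mbp 0.11 ± 0.30), the fibroblast genes Fmod and Col1a2 had 0.68 ± 0.12 and 0.365 ± 0.10, and Alas2 of red blood cells had -0.54 ± 0.14 (SE, n = 3 per group).

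The cholesterol list also fell in KO cerebellum. Its median log2 change was -0.195, with 6 of 7 genes lower (adjusted camera p = 9.78e-05, and adjusted p = 0.0255 with an estimated correlation). Idi1 had -0.38 ± 0.11, Cyp51 -0.33 ± 0.12, Hmgcs1 -0.22 ± 0.08, Msmo1 -0.195 ± 0.14, Nsdhl -0.16 ± 0.10 and Fdft1 -0.15 ± 0.14 (SE, n = 3 per group). Only Idi1 was in the authors' cerebellum list. The other 6 genes, not chosen on the cerebellum arrays, had a median of -0.18 with 5 lower. Their adjusted camera p was 0.00145 (adjusted p = 0.0310 with an estimated correlation), in a test added after the data were seen. No other list was tested there, so the adjustment changed nothing. These 6 genes had been chosen on hippocampus arrays of the same mice, so noise shared by the regions could carry their sign over. No member passed when adjusted over the list alone (0).

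No probe set passed the threshold in cerebellum (0 higher and 0 lower of 27022), with 1169 at an unadjusted limma p under 0.05 where 1351 would be expected. The smallest p among those higher belonged to Ctss, the protease inhibitor gene Cst3 at 0.67 ± 0.07, and 2 probe sets of Gfap at 1.16 ± 0.13 and 1.35 ± 0.15 (SE, n = 3 per group). Among those lower they belonged to a probe set with no gene name here at -2.64 ± 0.27, the transcriptional corepressor gene Tle6 at -0.95 ± 0.10, Nudt19 at -0.72 ± 0.09 and Pappa, a protease of IGF binding proteins, at -0.48 ± 0.09. Their adjusted p lay between 0.0603 and 0.432, so none passed. With 1 fit over all 12 arrays 31 passed as higher and 3 as lower. The array of KO replicate 1 had a Gapdh 3'/5' control ratio of 1.497, against 0.999 to 1.202 on the other 5 cerebellum arrays; without it 2 probe sets passed as higher, and the microglia median was 1.03.

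**Figure D2:**
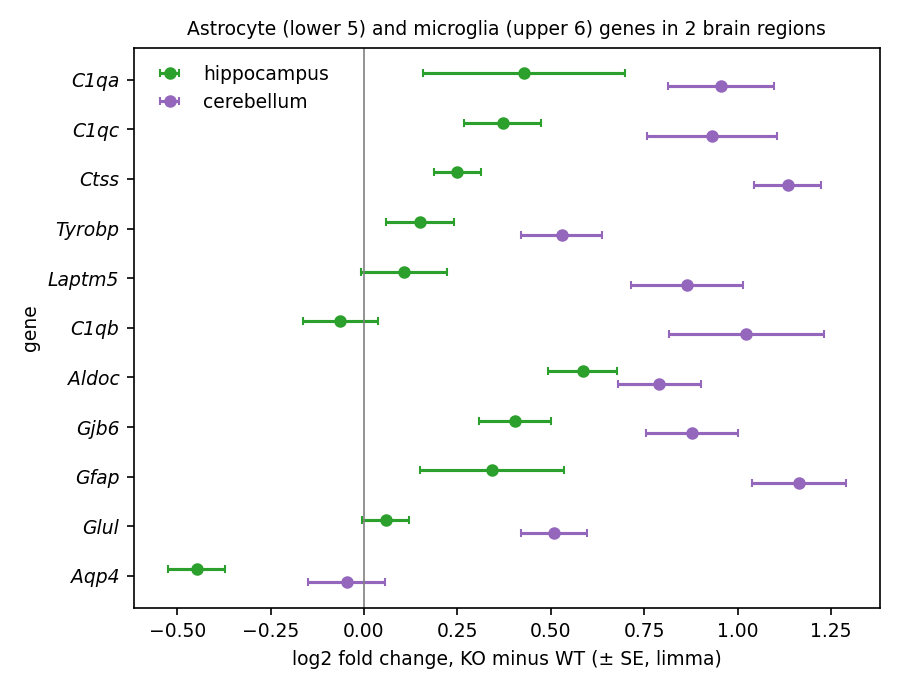
Log2 fold change (KO minus WT, horizontal axis) of 5 astrocyte and 6 microglia genes (vertical axis, 1 probe set each) in hippocampus (green) and cerebellum (purple), with the limma SE as bars, from 3 arrays per group. The 6 microglia genes lie between 0.53 and 1.13 in cerebellum and between -0.06 and 0.43 in hippocampus.

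**Figure D3:**
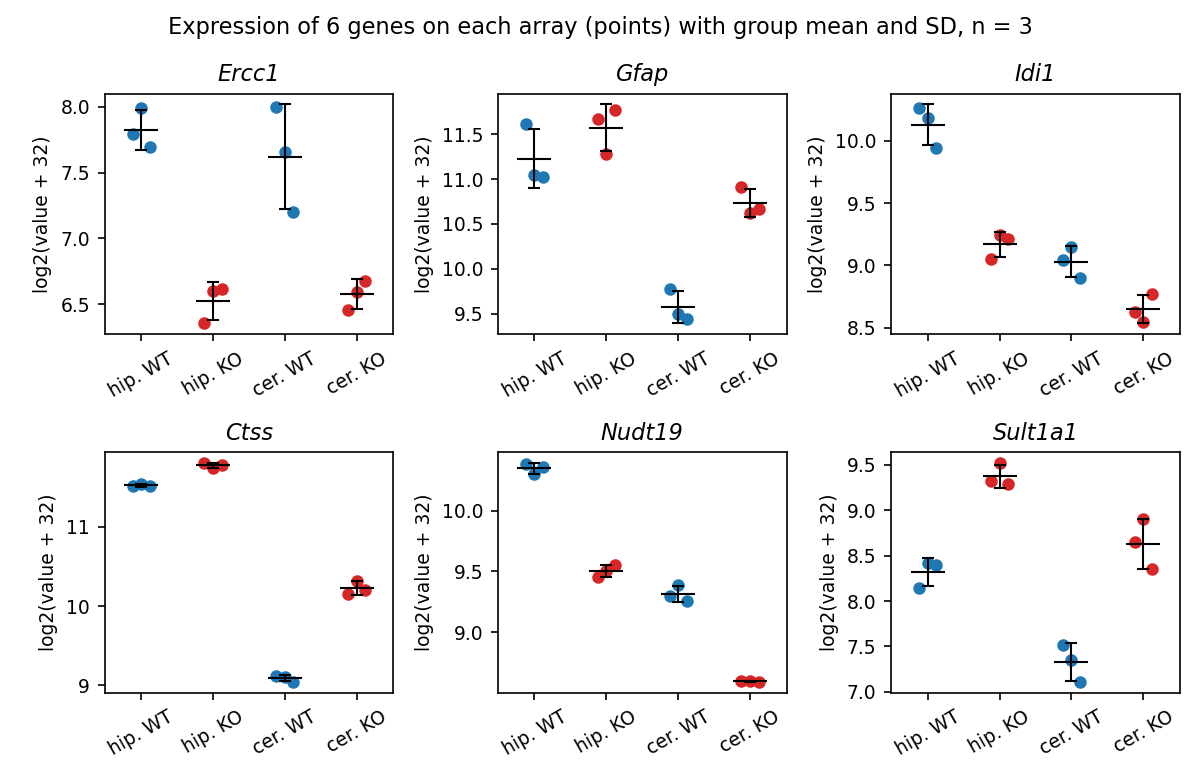
Values on each array as log2(value + 32) (vertical axes, a separate scale per gene) for 6 genes in the 4 groups (horizontal axes), with WT in blue and KO in red and black bars for the group mean and SD (n = 3). Ercc1, Idi1 and Nudt19 lie lower in KO in both regions, and Sult1a1 and Ctss higher. Levels of the separately deposited regions are not comparable.

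The KO effect of 1 probe set differed between the regions past the threshold. Ctss changed by 0.25 in hippocampus and 1.13 in cerebellum, a difference of -0.88 ± 0.10 (SE, adjusted p = 0.0306). The call ended when any of 10 of the 12 arrays was left out, such as hippocampus KO replicate 1 (adjusted p = 0.177), and with quantile normalization (adjusted p = 0.0557). It also ended with the replicate block (adjusted p = 0.281) and with mice as a block, if a number names a mouse (adjusted p = 0.613). Over all alternatives the adjusted p spanned 0.0138 to 0.613. As groups, the cholesterol genes had a median difference, hippocampus minus cerebellum, of -0.35 (adjusted camera p = 9.16e-09, and adjusted p = 0.00534 with an estimated correlation), the microglia genes -0.56 (adjusted p = 1.15e-16, and 0.00205 with an estimated correlation) and the astrocyte genes -0.45 (adjusted p = 1.40e-09, and 0.00166 with an estimated correlation). The members were chosen by the authors in 1 region or the other, which itself sets the regions apart. Over 23283 probe sets the regional log2 changes correlated at r = 0.18 across probe sets, which are not independent replicates; r was 0.02 without hippocampus WT replicate 1 and 0.04 without hippocampus KO replicate 2.

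The authors' deposited table for hippocampus lists 278 probe sets, 126 higher and 152 lower in KO, and that for cerebellum 367, 267 higher and 100 lower. Both were rebuilt in full from the deposited group means and standard errors with a fold of at least 1.2, a difference of at least 50 and an unadjusted p under 0.05 that allows unequal spread. In cerebellum the authors' standard errors equal the plain ones of 3 arrays, while in hippocampus the plain ones of WT are 0.909 times as large at the median. With plain means and standard errors of both groups 310 hippocampus entries would pass. Per the file footers the authors' permutations put the median false discovery rate at 55.8% in hippocampus and 23.7% in cerebellum, and its 90th percentile at 118.0% and 406.5%. All 278 and 367 entries had the same sign in limma, which selection on the same arrays fixes beforehand. Of them 275 and 364 entered the main fit, with 0 past the threshold.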

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

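The test of RNA quality, that of oligodendrocytes, the splits of each region's arrays for counts and the splits of mice over both regions were chosen after the result was seen, and the others were written down before.

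A test of the difference between regions was passed by 4 results: Ctss (-0.88), the cholesterol list (-0.35), the microglia list (-0.56) and the astrocyte list (-0.45), all hippocampus minus cerebellum on the log2 scale. The members of the 3 lists could be named only because the authors had selected them in 1 region or the other, so these list tests do not show by themselves that the regions differ. For astrocytes no draws from the authors' lists were made. The Ctss call ended when any of 10 of the 12 arrays was left out.

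The regional difference of the cholesterol genes does not stand out from that of other genes chosen in the same way. Its median of -0.35 lies at percentile 49.38 of 10000 equal-sized draws from the 107 other genes that are lower in the authors' hippocampus list. The median of those genes is also -0.35, so a stronger fall of the cholesterol genes in hippocampus is not set apart from selection. The other genes may differ between the regions themselves, so the draws do not measure selection alone. The array structure of hippocampus stays open. The median within the side nearest 0 is -0.456, but the genes were chosen on these arrays and have no overlap of KO and WT, so the value decides nothing. A lower share of oligodendrocytes is not decided. In hippocampus the 4 named myelin genes had a median of -0.33, which is 0.228 above the cholesterol median. This gap passes the margin written down for the test. It falls just short of the SD of 0.23 over these genes, a condition that was not written down. The test covers hippocampus only. In cerebellum the myelin median was 0.331 and the cholesterol median -0.195. The median difference between regions was -0.764 for the myelin genes and -0.348 for the cholesterol genes. Of the 10 splits of the mice, too few for a share under 0.05, 1 gave a regional difference as large, the real one (0.348, highest other 0.252).

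The regional difference of the microglia genes lies further out. Its median of -0.56 is at percentile 2.72 of draws from 210 other genes higher in the authors' cerebellum list, although genes of 1 cell type vary together and draws of unrelated genes understate that. The size of the cerebellum median does not rest on the single array with the higher Gapdh 3'/5' ratio, as it is 1.027 without that array against 0.93. The genes were chosen on these arrays and have no overlap of KO and WT there, so the sign was fixed beforehand. A large fall could hardly have been found, so the test decides little about RNA quality. An effect of genotype on microglia that is stronger in cerebellum stays a hypothesis. For Ctss and any other probe set, 1 of the 10 splits of the mice, the real one, gave the 1 call found (highest other 0), again too few for a share under 0.05.

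The hippocampus arrays part along a line that crosses genotype. KO 1, KO 3 and WT 1 against the others gives 3488 probe sets past the threshold, where KO against WT gives 0, which points to a structure of the samples. Scaling of whole arrays is argued against, as 3462 pass after quantile normalization, 3173 of them among the 3488 and with the same sign. RNA quality or labelling cannot be told apart from other sources: the deviation of WT hippocampus replicate 1 follows that of KO cerebellum replicate 1, the array with the high 3'/5' ratio (r = 0.655 over probe sets), but control values of hippocampus were not analysed here. No biological explanation was tested, since the line follows no group of the design.

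With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. All 10 gave at least the 0 calls of hippocampus (highest other 3488) and all 10 the 0 of cerebellum (highest other 10), which any split must. By an unadjusted limma p under 0.05, 5 of 10 splits reached the 1003 probe sets of hippocampus (highest other 7930). In cerebellum 4 of 10 reached the 1169 (highest other 4448). The real split alone, 1 of 10, reached the size of the cholesterol median in hippocampus (0.56 against 0.40 for the highest other), on genes chosen from that split, and 1 of 10 did so in cerebellum (0.195 against 0.173). Of the fixed lists 3 passed in each region, in 1 of 10 splits in hippocampus (highest other 2) and 2 of 10 in cerebellum (highest other 3).

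Both regions come from the same 6 mice, so splits over both regions moved the same replicate numbers in each, which holds only if a number names a mouse. Splits drawn separately in each region were run first and set aside, since they treat the regions as independent. Of 100 such splits 16 gave as many regional differences (highest other 4230), 26 as large a cholesterol difference (highest other 0.73) and 4 as many calls on the mean of both regions (highest other 1037).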

How the results depend on the processing

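Direction and side of the threshold held for the cholesterol list in each region and between regions under every alternative run for it. They also held with any array left out (hippocampus -0.65 to -0.47, cerebellum -0.25 to -0.17, between regions -0.45 to -0.29). In hippocampus the genes were chosen on these arrays and have no overlap of KO and WT, so leaving out an array could not change the direction. The test outside the authors' list could not be run there, as no measured member remains. The difference between regions rests on the same choice of genes. Of the counts, that on the mean of both regions moved under 8 of 10 alternatives and 11 of 12 left-out arrays, and that between regions under 8 of 11 and 12 of 12; the cause was not tested. The covariate, whose p-values are too small because it comes from the same residuals, the tests outside the authors' lists and the mean effect were added after the data were seen.

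In hippocampus 1 fit over all 12 arrays gave 1 higher and 5 lower, the covariate 5 and 3, and an unadjusted p under 0.05 with a 1.5-fold change 37 and 44. In cerebellum the same settings gave 31 and 3, 1 and 1, and 94 and 18; the stricter filter and the threshold of 0.10 gave 1 higher. Leaving out an array gave 0 to 2 higher and 0 to 2 lower in hippocampus, and 0 to 3 and 0 to 1 in cerebellum. The Ercc1 change of -1.30 in hippocampus passed in the fit over all arrays and with the covariate (-1.371 to -1.221 with an array left out).

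The count of 1 between regions became 0 with a pseudocount larger than 32, no filter, quantile normalization, median centring, no trend or mice as a block, 4 at 0.10 and 4 with the covariate, and 0 to 4 with an array left out. Of the 3 lists, 1 passed in hippocampus with an estimated correlation. Outside the authors' lists only 1 list per region had enough genes to be tested, and it passed in each. With an estimated correlation the hippocampus one did not (adjusted camera p = 0.0553). The genes of both tests had been chosen in the other region of the same mice. The correlation between regions was 0.016 to 0.265 with an array left out.

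Whether the replicate numbers pair KO with WT arrays is not settled. Deviations of same-numbered KO and WT arrays correlated at 0.688, 0.30 and -0.526 in hippocampus and 0.059, 0.348 and -0.234 in cerebellum. The deviations within a group sum to 0, so mixed signs do not decide it. Between the regions, where a number could name a mouse, same-numbered KO arrays correlated at 0.577, 0.537 and -0.273 and WT arrays at -0.022, 0.126 and -0.191, which leaves open whether it does. With the replicate block 0 probe sets passed in each direction in both regions, and the cholesterol medians were -0.557, -0.195 and -0.348. Between regions 1 probe set passed with that block, but not Ctss, whose adjusted p was 0.281 and whose call was lost. The value matrix as a source equals the region tables and was not run. Averaging probe sets of a gene was run for lists only, as other probe sets have no names.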

Other observations

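The tests of the mean of both regional effects, the splits of the mice and the genes named here were chosen after their values were seen.

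In the mean of both regional effects, 31 probe sets were higher and 7 lower in KO at an adjusted limma p under 0.05 of 23283 tested. A call on the mean is no call in each region: 28 of the 38 had an unadjusted p under 0.05 in both regions, 9 in cerebellum only and 1 in hippocampus only. Cst3 had 0.02 in hippocampus and 0.67 in cerebellum, and Tle6 had opposite signs, 0.10 and -0.95. Those higher in the mean include the astrocyte genes Gfap (0.75 ± 0.12, SE, for the brightest of 3 probe sets, and 1.004 ± 0.086 and 1.25 ± 0.10 for the others), Aldoc (0.69 ± 0.07) and Gjb6 (0.64 ± 0.08), the metallothionein genes Mt1 (0.42 ± 0.06) and Mt2 (0.40 ± 0.06), the complement gene C1qc (0.65 ± 0.11), Sult1a1 (1.18 ± 0.11), Etnppl (1.66 ± 0.20) and Trp53inp1, a p53 target (0.38 ± 0.06). The other measured p53 target of the fixed list, Phlda3, was not among the 38. It had -0.29 ± 0.11 in hippocampus and 0.44 ± 0.12 in cerebellum (SE). Those lower in the mean include Nudt19 (-0.78 ± 0.05) and Idi1 (-0.67 ± 0.08). The count of 38 was 12 with the replicate block, 19 without a filter, 22 with the stricter filter, 22 with median centring, 23 with a pseudocount of 1, 25 with quantile normalization, 64 at 0.10 and 106 with the covariate, and 12 to 34 with an array left out. Of the 10 splits of the mice, if a replicate number names a mouse, too few for a share under 0.05, 2 gave at least 38. The highest other, KO 2 exchanged with WT 1, gave 1037, which points to a structure of the samples. The 12 arrays come from 6 mice and were fitted as independent, so these p-values are too small if both regions of a mouse vary together. No fit of the mean took the mouse into account.

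The authors' deposited tables share 35 probe sets, of which 29 are higher in both regions, 4 lower in both and 2 opposite. Among 21484 probe sets whose higher group mean was at least 136.6 in both regions, independent lists would share 1.29 higher and 0.52 lower entries (Fisher's exact test, one-sided, p = 2.82e-31 and 0.00180). The test takes probe sets as independent, although some shared ones belong to the same gene, as for Gfap and Fam107a. Both regions come from the same mice, so the lists are not independent and these p-values do not measure a shared KO effect. Noise shared by same-numbered arrays stays a candidate explanation of the overlap and of the correlation between regions. Exchanging 1 KO with 1 WT number in both regions gave up to r = 0.586, above the real 0.177.

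Of the named myelin and fatty acid genes, too few for a list test, 3 had no overlap of KO and WT in either region. Over all probe sets tested, 8.9% had no overlap in hippocampus and 9.5% in cerebellum, against 10% by chance. The authors chose Ermn and Mal on cerebellum arrays and Scd1 on hippocampus arrays, which favours a lack of overlap there. Ermn had -0.75 ± 0.17 in hippocampus and 0.26 ± 0.10 in cerebellum, Mal -0.36 ± 0.12 and 0.52 ± 0.10, and Scd1, a desaturase, -0.46 ± 0.11 and 0.30 ± 0.11 (SE, n = 3 per group). The other 4 overlapped in 1 region: Mobp (-0.25 ± 0.14) and Elovl1 (-0.31 ± 0.17) in hippocampus, Mbp (0.11 ± 0.30) and Acly (0.15 ± 0.10) in cerebellum. None of the 7 passed over all probe sets. Of the sterol regulation genes, Insig1 had -0.43 ± 0.10 in hippocampus and -0.09 ± 0.15 in cerebellum, where the groups overlap, and Stard4 had -0.41 ± 0.12 and -0.28 ± 0.10. Neither passed.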
